A study of Mus musculus with 6 samples.

How the data were processed

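RNA samples were labelled as coming from 3 wild-type and 3 Eklf knockout fetal livers, at embryonic day 13.5, on a C57BL/6 background per the labels. Per the labels' protocols, liver cells were stained with 7AAD, a dye that enters dead cells, and with antibodies to CD71 and Ter119, which mark stages of red cell maturation, and early erythroid progenitors were sorted. Target was made from 10 micrograms of total RNA and hybridised to 1 single-colour Affymetrix array per sample. The labels call the 3 RNA samples of each genotype independent. The gates, the sorting yield, the position of the deletion and any date or batch of hybridisation are not given in the sources used here.

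The deposited values are intensity values on a linear scale, 1 per probe set, made with MAS5 and Affymetrix Expression Console per the submitters' processing notes, with versions not given in the sources used here. MAS5 subtracts a local background, combines the probe pairs of a probe set and scales each array. In the deposited table the mean of each array's values without the top and bottom 2% was 500, so every array was brought to 1 mean. This leaves the medians free to differ, and a sample with stronger bright signals is scaled down as a whole. Detection calls were not used here, so whether a dim signal lies above background was judged from its level alone.

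All 45101 probe sets were read. The annotation used listed 35890 of them, 34958 with 1 gene and 932 with several, and 9211 were not listed and stay unnamed. Gene symbols were updated through Entrez identifiers to RefSeq, which matched 34754 probe sets. No gene was named from a probe set that lists several genes. This left 18193 genes, each taken at its probe set with the highest mean log2 signal over the 6 arrays. The 64 Affymetrix control probe sets were kept out of the gene tests. Probe sets of 1 gene can disagree: 65 of the 156 named genes had other probe sets above the filter, and for 16 at least 1 of these went the opposite way. Where the mean of a gene's probe sets is used below, it covers all of them, also those under the filter.

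Signals under 1 were set to 1 (303 values) and log2 was taken, with no further scaling. Genes with a mean log2 signal under the 40th percentile of all probe sets, 6.62 or a signal of 98.6, were left out, and 12799 genes were tested. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend in the prior variance), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. Every adjusted p given for a gene is limma's. Differences are knockout-labelled minus wild-type-labelled on the log2 scale. For Klf1 an exact permutation test of the 6 values was added. No pair of arrays held identical values. Correlations of log2 signals over all probe sets ran from 0.922 to 0.944 within the wild-type-labelled arrays, from 0.897 to 0.906 within the knockout-labelled arrays and from 0.822 to 0.858 between groups.

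Gene lists were tested with limma's camera at its preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 30 lists, and again with an estimated correlation and with fry, which tests whether the genes of a list move one way on balance. The lists, the comparison and the rule for named genes were fixed before the data were examined. The rule took Klf1, the 15 genes with the largest decrease and the 15 with the largest increase among called genes whose groups did not overlap, up to 4 members of each list with the smallest p, and a fixed set of erythroid and cell cycle genes. Predicted genes and clone names were left out of it. Some genes of the fixed set were not analysed here, among them Ahsp, Hbb-b1, Hbb-bs, Hbb-bt, Bnip3l and Trim58. Alas1, Xiap, Alb, Afp, Mpo, S100a8, S100a9, C1qb, C1qc and Ccr2 were named outside the rule, after their values were seen, as were the genes of the closing observations.

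The tests were tried on simulated data with the real means and spreads of the 12799 genes. With 50 genes changed per size, 62% of log2 changes of -2 and 70% of changes of 2 were recovered, and 28% of changes of -1 and of 1. There were 4 false calls, 4.08% of all calls. With 1 of the 30 lists shifted, camera called 1. Genes were drawn independently of each other, so this does not test the preset correlation on the real data. A far smaller share of genes was changed than the 48.7% called in the data, so recovery may differ there. Alternatives were quantile normalization, median centring, offsets of 16 and 64, other intensity filters, other variance models, array weights, other choices of probe set, the replicate number as a block, each array left out in turn, stricter thresholds and, chosen after seeing the data, cyclic loess and a fit with knockout-labelled array 1 as the lone array of its group. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.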

Results

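Gene expression was measured on 6 Affymetrix mouse arrays, each hybridised with RNA from erythroid progenitors sorted by flow cytometry from fetal liver at embryonic day 13.5, where the labels name 1 liver per array. Of these arrays 3 were labelled wild type and 3 were labelled as homozygous for the Eklf knockout. Eklf, whose gene symbol is Klf1, encodes a zinc finger transcription factor of the red cell lineage. The 1 comparison of the design asks how the transcripts of early erythroid progenitors differ when this factor is lost. Each array gave a signal for 45101 probe sets with a trimmed mean of 500. The median signal was 128, 140 and 97.7 on the wild-type-labelled arrays and 204, 218 and 214 on the knockout-labelled arrays. The number of arrays, 3 per group, limits the precision of every difference given here.

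On the knockout-labelled arrays embryonic globin transcripts were higher, as were 18 of 26 haem and iron genes, 21 of 28 red cell enzymes and 18 of 26 megakaryocyte genes. Lower were 17 of 27 stem and progenitor genes, 22 of 45 DNA replication genes and 10 of 15 E2F family genes. Each of these lists passed camera with a preset correlation, and with an estimated correlation 0 of them passed (adjusted p 0.138 to 0.464). The embryonic beta-like globin Hbb-y stood at 49920 ± 17256 (SD, n = 3) against 1032 ± 620 on the wild-type-labelled arrays, and Alas2, the first enzyme of erythroid haem synthesis, was 15.3-fold higher. Kit, the receptor for stem cell factor, was 3.32-fold lower, and Myb, a transcription factor of immature haematopoietic cells, was 4.13-fold lower. Markers of other cells moved with the same grouping. Of 25 tested hepatocyte markers 24 were higher on the knockout-labelled arrays, and of 19 lymphoid markers 15 were lower.

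Klf1 itself did not separate the groups. Its probe set, the 1 listed for it, gave 2508, 2706 and 4030 on the wild-type-labelled arrays and 3505, 1391 and 2545 on the knockout-labelled ones. The means were 3081 ± 827 and 2480 ± 1058 (SD, n = 3), a log2 difference of -0.38 ± 0.32 (SE, limma adjusted p = 0.347). An exact two-sided permutation test of the 6 values gave p = 0.5, where the smallest p that 3 against 3 arrays allow is 0.1. Over 20 alternative fits the limma adjusted p of Klf1 ran from 0.0128 to 0.972. The lowest came after median centring, which lowered all genes (Klf1 difference -1.20). With knockout-labelled array 1 as the lone array of its group the difference was 0.22. Which part of the gene this probe set covers, relative to the deleted part, is not known from the sources used here. A probe set outside the deleted part would check nothing, so the groups are called by their labels throughout.

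**Figure D1:**
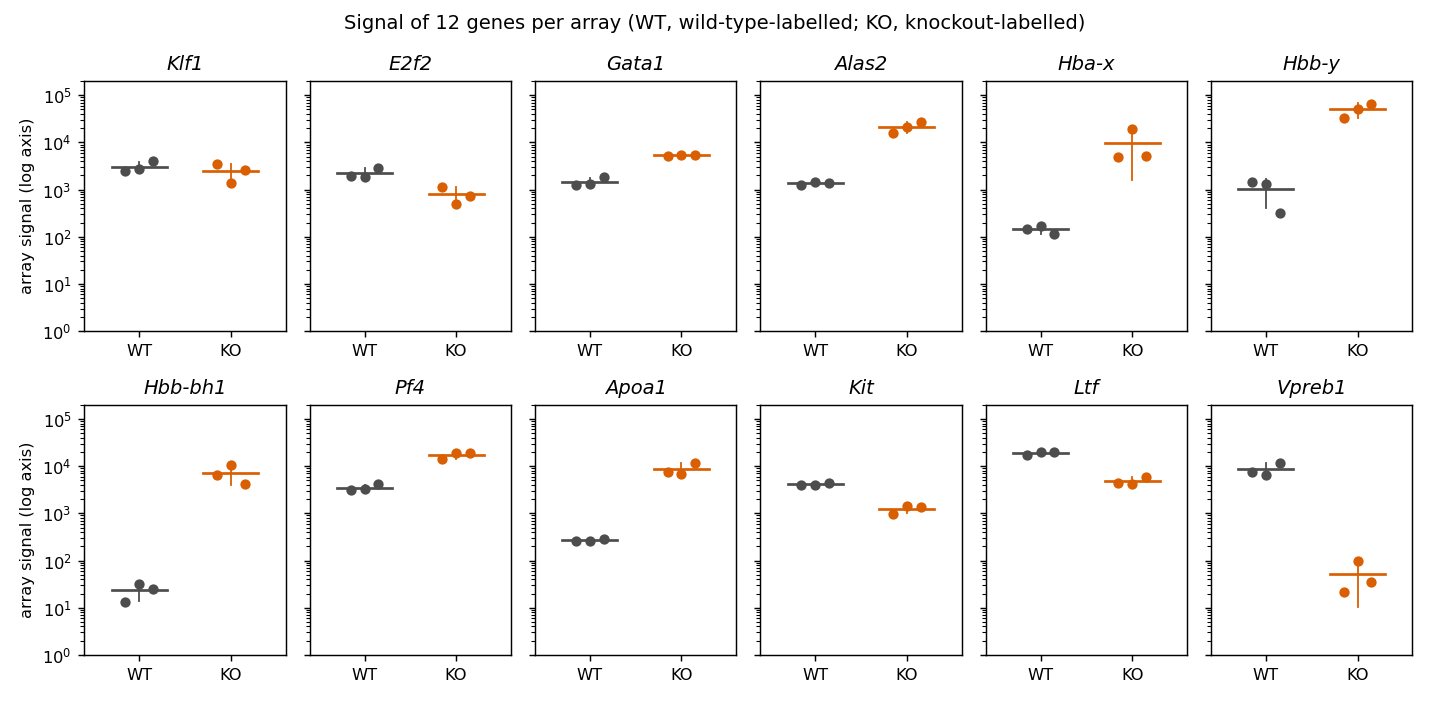
Array signal of 12 genes on a log axis, with 1 point per array, a horizontal line at the mean of 3 arrays and a vertical line of 1 SD. Klf1 overlaps between wild-type-labelled (WT) and knockout-labelled (KO) arrays, while Hbb-y has means of 1032 and 49920 and Vpreb1 has means of 8588 and 52.2.

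Of 12799 genes tested with limma, 6232 (48.7%) differed between the groups at an adjusted p under 0.05. Of these 3571 were higher and 2661 lower on the knockout-labelled arrays, so that 57.3% of the calls were higher. At least a 2-fold change was seen in 4024 of them, 2620 higher and 1404 lower. The 3 values of each group did not overlap for 7587 genes (59.3%), where chance gives 10%, and 7206 genes passed an unadjusted p under 0.05. The direction of the calls changed with brightness and with scaling. Among the 3200 dimmest genes the median log2 difference was 0.94, with 1426 higher and 183 lower calls, and among the 3201 brightest it was -0.25, with 484 higher and 1129 lower calls. The share of higher calls was 44.8% after quantile normalization (2224 higher, 2740 lower), 46.3% after cyclic loess (2292 higher, 2658 lower) and 15% after median centring (1085 higher, 6133 lower). The median difference over all genes was 0.14 as deposited and -0.68 after median centring, and list shifts below are tests against all other genes. A gene whose lower group lies near the filter, at a signal of 98.6, has a fold that rests on a dim value, as for 1090 of the calls.

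Of the 30 gene lists fixed in advance, 18 differed from the other genes by limma's camera with a preset correlation, 8 upward and 10 downward. With an estimated correlation 0 of them passed, and the directional fry test called 19. The adjusted p with an estimated correlation is therefore given beside each list that camera called. Without adjustment, 8 of the 30 lists passed with an estimated correlation.

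**Figure D2:**
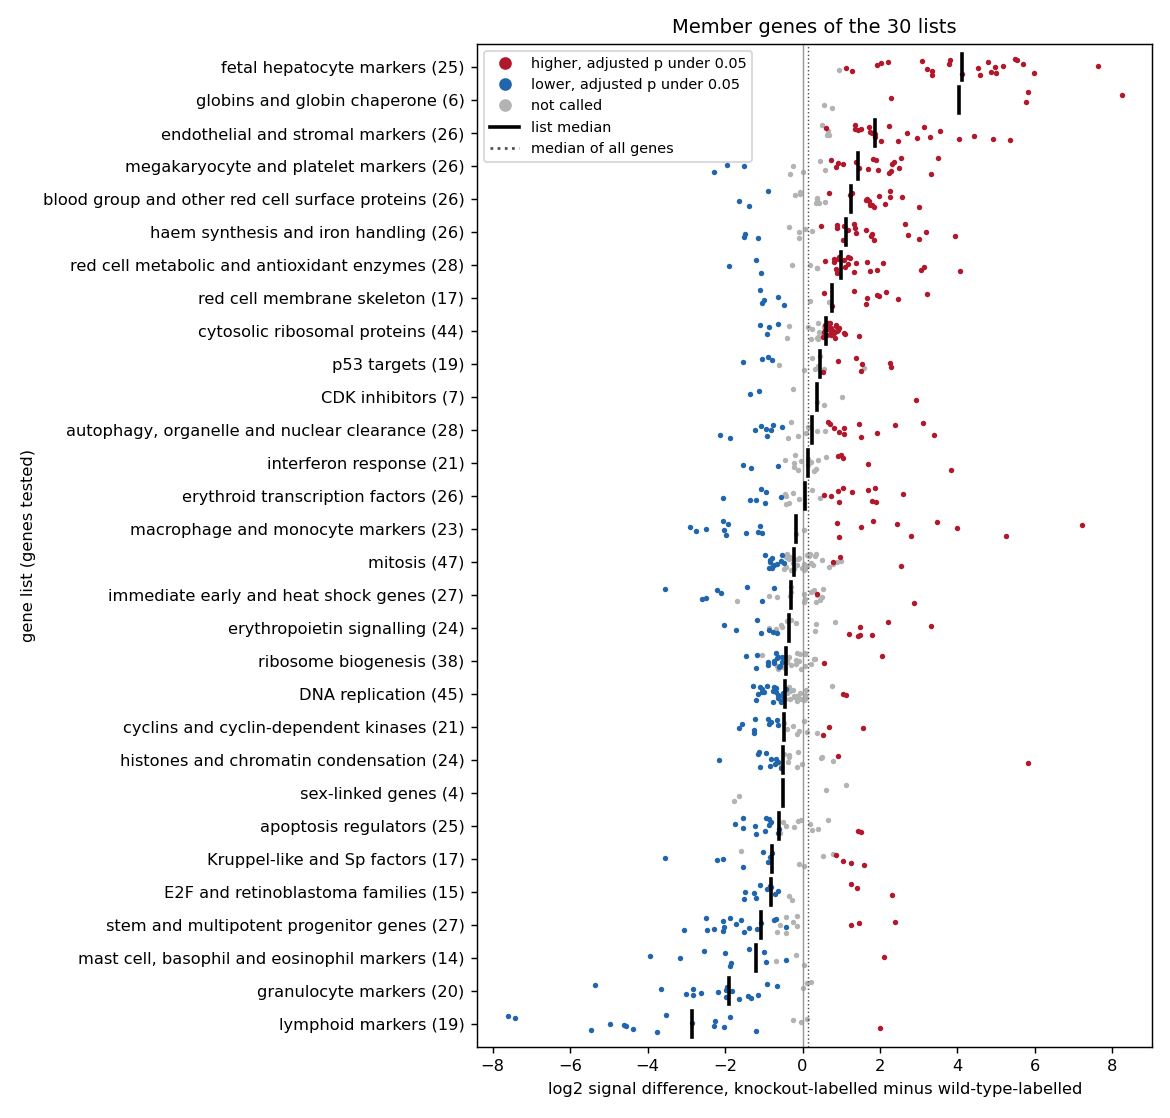
Log2 signal difference (knockout-labelled minus wild-type-labelled) of each tested member of the 30 gene lists, 1 point per gene, coloured by its call at an adjusted p under 0.05. Black bars mark list medians, which run from -2.85 for lymphoid markers to 4.11 for fetal hepatocyte markers, and the dotted line marks the median of all genes at 0.14.

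Genes of the mature red cell were mostly higher on the knockout-labelled arrays. Of the 6 globin genes with a probe set of their own, 4 rose, 4 when adjusted over the list alone (camera adjusted p = 0.000997; adjusted p = 0.151 with an estimated correlation). The rise was led by the embryonic globins Hbb-bh1 (log2 difference 8.24 ± 0.40, SE), Hbb-y (5.81 ± 0.52) and Hba-x (5.78 ± 0.46), whose 7 probe sets were 54.8- to 584-fold higher. The wild-type signal of Hbb-bh1 was 23.2 ± 9.25 (SD, n = 3), under the filter. Hbb-b2, an adult beta-like globin, rose by 2.30, and its other probe set gave 0.62. Hba-a1, an adult alpha globin, did not pass the test at 0.75 ± 0.36 (adjusted p = 0.108), and its difference was -0.097 after quantile normalization, -0.13 after cyclic loess and -0.066 after median centring. It passed in 2 of 19 alternatives, without a variance trend (adjusted p = 0.0245) and with array weights (0.044). The probe set of Hba-a1 was dim, with means of 94.3 (wild-type-labelled) and 156 (knockout-labelled). Probe sets shared by the adult alpha globin genes had wild-type-labelled means of 3760 to 23525. The Hba-a1 result therefore does not show whether adult alpha globin RNA changed. The 4 probe sets shared by several adult globin genes were 1.83-, 1.93-, 2.1- and 15.4-fold higher and were not tested. Their knockout-labelled means, 33818 to 60321, lay near the top of the scale, which compresses such folds. The hybridisation controls, added in fixed amounts, were 1.6- to 4.16-fold higher. The folds of 1.83 to 2.1 lie within that range and so do not show a rise of adult globin RNA. Hepatocyte, stromal and megakaryocyte markers were higher in the same direction.

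Of 26 tested haem and iron genes 18 rose and 3 fell, the same counts when adjusted over the list alone (camera adjusted p = 0.000133; adjusted p = 0.332 with an estimated correlation). Alas2 rose from 1357 ± 107 to 21163 ± 5508 (SD, n = 3), a log2 difference of 3.93 ± 0.20 (SE, adjusted p = 3.62e-06). Fech, the enzyme that inserts iron into the porphyrin ring, rose by 2.72, Uros, an earlier enzyme of the pathway, by 2.65, and Abcg2, a porphyrin exporter, by 3.00. Alas1, the enzyme used outside the red cell lineage, fell by 1.51. Tfrc, which encodes the transferrin receptor CD71 used in the sort, rose by 0.47 ± 0.14 (SE, adjusted p = 0.0238). Its 2 other probe sets gave 1.15 and 1.44. The Affymetrix control probe sets for the transferrin receptor, kept out of the gene tests, gave 1.53, 1.845 and 1.604. The call was lost in 4 of the 6 fits that left out 1 array (adjusted p 0.0544 to 0.0609) and in 7 of all 20 alternatives, and the difference was -0.35 after median centring.

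Among red cell enzymes 21 of 28 rose and 3 fell, again the same when adjusted over the list alone (camera adjusted p = 0.000133; adjusted p = 0.464 with an estimated correlation). Bpgm, which makes 2,3-bisphosphoglycerate, rose by 4.05, Car1, a carbonic anhydrase, by 3.07, and Gclm, a subunit of the first enzyme of glutathione synthesis, by 3.13. Of 26 red cell surface genes 15 rose and 3 fell, 17 and 3 when adjusted over the list alone (camera adjusted p = 0.000559; adjusted p = 0.316 with an estimated correlation). Kel, the Kell blood group protein, rose by 2.58, Xk by 2.25 and Rhag, the Rh-associated glycoprotein, by 1.99. Cd44, an adhesion receptor, fell by 1.63 and Aqp1, a water channel, fell by 1.38. Icam4, a red cell adhesion molecule, did not pass the test at 0.37 ± 0.28 (SE, adjusted p = 0.287).

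The membrane skeleton list was split: 10 of 17 members rose and 5 fell, 11 and 5 when adjusted over the list alone. As a set it did not pass camera (adjusted p = 0.0552), and over 22 alternatives the adjusted p ran from 0.0021 to 0.681. It passed upward in 12 of them, including quantile normalization (0.00666), cyclic loess (0.0021), median centring (0.0183) and 3 of the 6 fits that left out 1 array (0.0242 to 0.0491). Sptb, beta spectrin, rose by 3.21, Epb42, protein 4.2, by 2.46, Slc4a1, the anion exchanger band 3, by 1.92, and Add2, beta adducin, by 1.65. Dmtn, dematin, fell by 0.99 (SE 0.20), while another of its probe sets gave 0.56. The call of Dmtn was lost with the mean of its probe sets (adjusted p = 0.206), and that of Add2 after median centring (0.0539). Ank1, erythroid ankyrin, did not pass at 0.68 ± 0.26 (adjusted p = 0.0517), while its 3 other probe sets gave 1.56 to 2.36. Over 20 alternatives its adjusted p ran from 0.00077 to 0.747. It passed in 9 of them, among them the mean of its probe sets (1.57) and 2 of the 6 fits that left out 1 array (adjusted p 0.0172 and 0.0204).

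Erythroid transcription factors moved both ways, with 11 of 26 higher and 7 lower (12 and 9 when adjusted over the list alone; camera adjusted p = 0.923). Gata1, the central activator of erythroid genes, rose from 1462 ± 320 to 5349 ± 104 (SD, n = 3), its cofactor Zfpm1 by 1.87, Gfi1b, a repressor, by 1.80, and Tal1, a partner of Gata1, by 1.68. Bcl11a, a repressor of embryonic and fetal globin genes, fell by 0.96 and Ikzf1 fell by 1.36, although another Ikzf1 probe set gave 0.25. Klf3, a repressor related to Klf1, fell by 2.04, while 1 of its 4 other probe sets above the filter gave 0.76. The mean over all Klf3 probe sets, among them dim ones under the filter, did not pass (-0.34, adjusted p = 0.28).

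Of 24 erythropoietin signalling genes 7 rose and 7 fell (8 and 7 when adjusted over the list alone). This list's median was -0.34, its mean 0.11, camera placed it downward (adjusted p = 0.703) and fry upward (adjusted p = 0.152). Epor, the erythropoietin receptor, rose by 1.49, Cish, a target of its signal, by 1.79, Podxl by 3.32, Spry1 by 2.22 and Bcl2l1, which encodes the survival protein Bcl-xL, by 1.42. After median centring the calls of Epor (adjusted p = 0.0616) and Bcl2l1 (0.111) were lost. Of 28 genes of autophagy and organelle clearance 12 rose and 9 fell (13 and 9 when adjusted over the list alone; camera adjusted p = 0.703). Bnip3 rose by 3.40, Ube2o, a ubiquitin ligase of reticulocytes, by 3.12, and Trim10 by 2.40.

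Of the 15 genes of the E2F and retinoblastoma families 10 fell and 3 rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.0265; adjusted p = 0.396 with an estimated correlation). E2f2, an activator of S-phase genes, fell from 2217 ± 622 to 797 ± 323 (SD, n = 3), a log2 difference of -1.52 ± 0.30 (SE, adjusted p = 0.00337). E2f7 fell by 1.25 and Tfdp1, the dimer partner of E2F proteins, fell by 1.10, while Rb1 rose by 1.40 and Tfdp2 by 1.26. E2f4 did not pass the test at -0.35 ± 0.32 (adjusted p = 0.38), and it passed when knockout-labelled array 1 was left out (adjusted p = 0.0447) and after median centring (0.0138). After median centring the calls of Rb1 (adjusted p = 0.0593) and Tfdp2 (0.143) were lost. The call of this list was lost in 7 of 22 alternatives, among them quantile normalization (adjusted p = 0.119), cyclic loess (0.0945), median centring (0.104) and the mean of probe sets (0.064). With knockout-labelled array 1 as the lone array of its group it was lost too (0.132), as were the calls of E2f2 (0.0951), Rb1 (0.0573), Tfdp1 (0.0543) and Tfdp2 (0.0514).

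Of 45 DNA replication genes 22 fell and 2 rose, 23 and 2 when adjusted over the list alone (camera adjusted p = 3.99e-05; adjusted p = 0.396 with an estimated correlation). Uhrf1, which recruits DNA methyltransferase, fell by 1.28. Dut, a dUTPase, fell by 1.21 and Orc6, of the origin recognition complex, fell by 1.14. Among cyclins and their kinases 10 of 21 fell and 3 rose, the same when adjusted over the list alone (camera adjusted p = 0.00988; adjusted p = 0.464 with an estimated correlation). Cdc25a, a phosphatase of the G1 to S transition, fell by 1.65 and Cdk6 fell by 1.55, although another Cdk6 probe set gave 1.34. With the mean of its probe sets Cdc25a did not pass (-0.69, adjusted p = 0.0702). Its other probe set above the filter gave -1.15, and a dim probe set under the filter (means 76.5 and 143) gave 0.72. Cdc25b, a phosphatase of mitotic entry, rose by 1.57, a call lost after median centring (adjusted p = 0.0648). The cyclin list lost its call in 5 of 22 alternatives, among them quantile normalization (adjusted p = 0.209), cyclic loess (0.234) and knockout-labelled array 1 as the lone array of its group (0.132).

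Of 47 mitosis genes 12 fell, 3 rose and 32 did not pass (10 and 3 when adjusted over the list alone). The set did not pass camera (adjusted p = 0.0732), and over 22 alternatives the adjusted p ran from 0.00819 to 0.9. It passed in 4 of them, among them the fit without wild-type-labelled array 3 (0.00952). Under quantile normalization (0.013) and cyclic loess (0.0047) its median lay slightly above that of all genes. Spc24, a kinetochore protein, fell by 0.96, and Pttg1, securin, rose by 0.97, a call lost after median centring (adjusted p = 0.648). Cit rose by 2.54, while 1 of its 3 other probe sets gave -1.19. Of 7 inhibitors of cyclin-dependent kinases 1 rose and 2 fell, the same when adjusted over the list alone (camera adjusted p = 0.927, downward, against a median of 0.38 and a mean of 0.31). Cdkn1c, the inhibitor p57, rose by 2.93, and Cdkn2c, p18, fell by 1.35. Cdkn1a, p21, did not pass at 0.57 ± 0.38 (adjusted p = 0.234) or Cdkn1b, p27, at 0.38 ± 0.16 (0.0751). Cdkn1a passed without knockout-labelled array 1 (adjusted p = 0.00766) and Cdkn1b without wild-type-labelled array 3 (0.0465). Over 20 alternatives Cdkn1a passed in 2 and Cdkn1b in 5, with its other probe set at 2.16 and the mean of both at 1.27 (adjusted p = 0.00249), and after median centring both were below 0 (-0.25 and -0.43).

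Of 25 apoptosis regulators 12 fell and 2 rose, the same when adjusted over the list alone (camera adjusted p = 0.00542; adjusted p = 0.138 with an estimated correlation). The members that fell act in both directions. Casp8, an initiator caspase, fell by 1.73 and Apaf1, of the apoptosome, fell by 1.20. Among caspase inhibitors, Xiap fell by 0.94 and Birc3 fell by 1.53. The other Birc3 probe set gave 1.31, and the mean of both did not pass (-0.11, adjusted p = 0.885). With the mean of probe sets the apoptosis list lost its call (adjusted p = 0.052). Of 19 p53 targets 7 rose and 4 fell, 8 and 4 when adjusted over the list alone (camera adjusted p = 0.429; fry upward, adjusted p = 0.0336). Gadd45a rose by 2.29 and Plk2 by 2.27, while Sesn1 fell by 1.04, with 1 of its 3 other probe sets at 1.46.

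Stem and multipotent progenitor genes were lower: of 27 tested 17 fell and 3 rose, the same when adjusted over the list alone (camera adjusted p = 1.13e-05; adjusted p = 0.138 with an estimated correlation). Kit fell from 4086 ± 191 to 1245 ± 228 (SD, n = 3) and Myb from 10727 ± 868 to 2612 ± 368. Erg and Fli1, ETS factors of stem cells and megakaryocytes, were lower too (log2 differences -2.47 and -2.30). Sox4 fell by 2.50, while the largest of its 2 opposite probe sets gave 2.37 and the mean of its probe sets did not pass (-0.57, adjusted p = 0.0809). Gata2, a factor of early progenitors, fell by 0.43 (adjusted p = 0.0414; its other probe set gave -0.92), a call lost in 10 of 20 alternatives, 5 of them among the 6 fits that left out 1 array (adjusted p 0.0686 to 0.159). Granulocyte, lymphoid and mast cell markers were lower on the same arrays, and Kit, Gata2 and Fli1 are expressed in some of those cells or in megakaryocytes.

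Of 26 megakaryocyte and platelet markers 18 rose and 3 fell, the same when adjusted over the list alone (camera adjusted p = 0.000311; adjusted p = 0.138 with an estimated correlation). Pf4, platelet factor 4, rose from 3471 ± 551 to 17219 ± 2846 (SD, n = 3), Itga2b, the platelet integrin subunit CD41, by 2.49, Ppbp by 2.37 and Vwf, von Willebrand factor, by 3.50. Vwf is also made by endothelial cells, whose markers rose as well. Fli1, an activator of megakaryocyte genes, was among the 3 that fell.

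Markers of hepatocytes and of endothelial and stromal cells, which are cells of the fetal liver, were higher on the knockout-labelled arrays. Of the 29 and 27 members of these lists 0 belonged to another list. Of 25 hepatocyte markers 24 rose, the same when adjusted over the list alone (camera adjusted p = 5.27e-16; adjusted p = 0.138 with an estimated correlation). Albumin (Alb) stood at 2272 ± 164 and 40107 ± 11164 (SD, n = 3) and alpha-fetoprotein (Afp) at 3472 ± 59.1 and 36420 ± 12572. Fgb, a fibrinogen chain, rose by 7.63, from a wild-type signal of 27.6 ± 24.3, under the filter. Of 26 endothelial and stromal markers 22 rose, 23 when adjusted over the list alone (camera adjusted p = 5.46e-09; adjusted p = 0.138 with an estimated correlation). The collagen genes Col1a1, Col3a1 and Col1a2 rose by 5.36, 4.91 and 4.04. Genes with the largest increases outside the lists included Igfbp1 (8.40), Itih3 (6.41), Plg, which encodes plasminogen (5.52), Slc27a2 (5.60) and the imprinted RNA Meg3 (6.19). The mean wild-type signals of Igfbp1 (64.6), Itih3 (38.4), Slc27a2 (17.0) and Col1a1 (79.6) were under the filter, so their folds rest on dim values.

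Markers of lymphoid and granulocytic cells were lower on the knockout-labelled arrays. Of the 24 and 22 members of these lists 0 belonged to another list. Of 19 lymphoid markers 15 fell and 1 rose, the same when adjusted over the list alone (camera adjusted p = 1.45e-08; adjusted p = 0.138 with an estimated correlation). Vpreb1, part of the surrogate light chain of B cell precursors, stood at 8588 ± 2910 and 52.2 ± 41.8 (SD, n = 3), and Rag1, a recombinase of antigen receptor genes, at 3066 ± 159 and 28.6 ± 28.6. Igll1 fell by 4.98, Cd79a fell by 5.46 and Ighm fell by 4.60. Of the 4 other Ighm probe sets above the filter, 3 went the opposite way and 1 gave -5.92. The mean over all Ighm probe sets, among them dim ones under the filter, did not pass (-0.033, adjusted p = 0.943). Of 20 granulocyte markers 17 fell, the same when adjusted over the list alone (camera adjusted p = 7.03e-09; adjusted p = 0.332 with an estimated correlation). Ltf, lactoferrin, fell from 18661 ± 1533 to 4789 ± 955 and Mmp8, a neutrophil collagenase, from 6443 ± 1818 to 508 ± 85.5, while Mpo, S100a8 and S100a9 did not pass (log2 differences 0.02, 0.10 and 0.22).

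Of 14 mast cell, basophil and eosinophil markers 10 fell and 1 rose, the same when adjusted over the list alone (camera adjusted p = 0.000133; adjusted p = 0.138 with an estimated correlation). Mcpt8, a basophil protease, fell by 3.95 and Hdc, histidine decarboxylase, fell by 3.17. Macrophage and monocyte markers were divided, with 10 of 23 higher and 11 lower, the same when adjusted over the list alone (camera adjusted p = 0.43). The median of this list was -0.16 and its mean 0.41, with camera downward. Marco, a scavenger receptor, rose by 7.21, from a wild-type signal of 9.25 ± 2.07 (SD, n = 3), under the filter. Hmox1, haem oxygenase, rose by 3.99 and the complement genes C1qc and C1qb by 5.24 and 2.80. Cybb, of the phagocyte oxidase, fell by 2.75, Ly86 fell by 2.91 and Ccr2, a monocyte chemokine receptor, fell by 1.97.

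Ribosomal protein genes rose in 26 of 44 cases and fell in 4, 30 and 5 when adjusted over the list alone (camera adjusted p = 0.00323; adjusted p = 0.681 with an estimated correlation), a shift that turned to -0.046 after quantile normalization and a call lost in 5 of 22 alternatives, among them median centring (adjusted p = 0.228). Ribosome biogenesis genes fell in 14 of 38 cases and rose in 2, 14 and 1 when adjusted over the list alone (camera adjusted p = 0.00158; adjusted p = 0.464 with an estimated correlation), a call lost after quantile normalization (adjusted p = 0.116) and cyclic loess (0.159) among 5 of 22 alternatives. Of 24 histone and chromatin genes 11 fell and 2 rose, the same when adjusted over the list alone (camera adjusted p = 0.00798; adjusted p = 0.174 with an estimated correlation), a call lost after quantile normalization (adjusted p = 0.113) and cyclic loess (0.202) among 5 of 22 alternatives. Smarca4, the ATPase of a chromatin remodelling complex, fell by 1.11, and the linker histone gene H1f4 rose by 5.83.

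Krüppel-like and Sp factor genes fell in 8 of 17 cases and rose in 4, the same when adjusted over the list alone, and the set did not pass camera (adjusted p = 0.117) but passed fry (0.00167). Klf4 fell by 3.56 and Klf10 fell by 1.53. Of 27 immediate early and heat shock genes 8 fell and 2 rose, 7 and 1 when adjusted over the list alone (camera adjusted p = 0.102). This set passed in 6 of 22 alternatives, among them the fits without wild-type-labelled array 1 (adjusted p = 0.02) or 2 (0.0202). Its shift against all genes was -0.44, and without wild-type-labelled array 3 it was 0.16 (adjusted p = 0.804). Of 21 interferon response genes 5 rose and 3 fell, the same when adjusted over the list alone (camera adjusted p = 0.809). None of the 4 sex-linked genes tested passed the test, over all genes or adjusted over the list alone (camera adjusted p = 0.923, downward, with fry upward at 0.982), and 0 of them passed an unadjusted p under 0.05. Eif2s3y, a Y-linked gene, and Xist passed when knockout-labelled array 2 was left out (limma adjusted p = 0.0128 and 0.0026). The wild-type-labelled arrays each carried signal for both Xist (6521, 7559 and 4067) and Eif2s3y (484, 456 and 178). On the knockout-labelled arrays Xist stood at 17502, 4592 and 25611 and Eif2s3y at 75.9, 1328 and 9.69. Whether each array holds cells of 1 embryo is therefore left open, although the labels name 1 liver for each.

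Control probe sets also separated the groups. The 3 probe sets for 18S ribosomal RNA were 317- to 502-fold higher on the knockout-labelled arrays, from wild-type-labelled values of 10.98 to 187, most of them under the filter. The 18 hybridisation controls, which are added in fixed amounts, were 1.6- to 4.16-fold higher. Of 27 probe sets for polyadenylated bacterial control RNA, 19 had all 3 knockout-labelled values above all 3 wild-type-labelled ones, where chance gives 5%. Their wild-type-labelled means were dim (2.245 to 52.56), and several of these probe sets report the same control RNA. The ratio of 3' to 5' signal, knockout-labelled over wild-type-labelled, was 0.97 for Gapdh and 0.949 for beta-actin, but these probe sets lie near the top of the scale, which compresses it. For the dimmer controls of transferrin receptor and pyruvate carboxylase it was 0.804 and 1.08, with SEs of 0.377 and 0.316 log2 units, too wide to exclude degraded RNA. These 2 were examined after the first 2 had been seen. On knockout-labelled array 1 hybridisation controls were 0.853- to 1.99-fold, bacterial control RNA 0.579- to 57.3-fold and 18S 69.8- to 268-fold the wild-type-labelled level, and with it as the lone knockout-labelled array 2603 genes were called. No date or batch is given in the labels used here, so processing and group cannot be told apart.

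**Figure D3:**
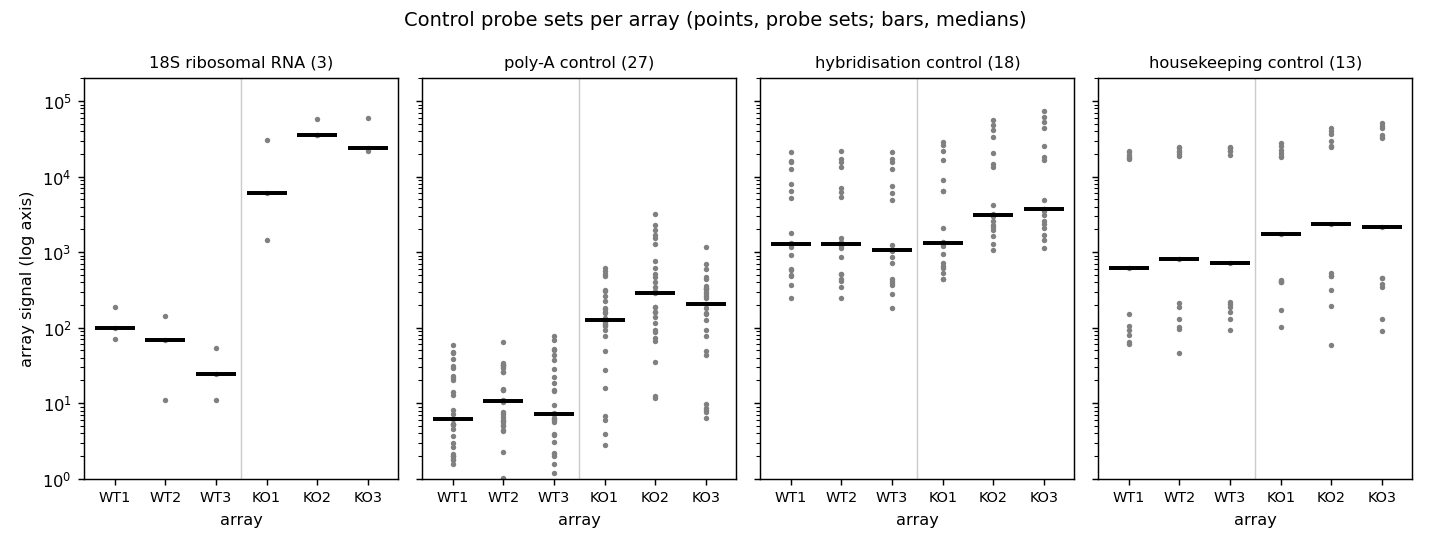
Array signal of the control probe sets on a log axis, with 1 point per probe set and a bar at the median of each array (WT, wild-type-labelled; KO, knockout-labelled; the number gives the array). The 3 probe sets for 18S ribosomal RNA are 317- to 502-fold higher on the knockout-labelled arrays.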

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

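The tests of different cells in the sort, of intensity-dependent scaling, of a single scaling factor, of degraded RNA, of separate processing and of cross-hybridisation were chosen only after the result was seen; the test of the 10 splits and those of developmental stage and of mature erythroid share were set before. No gene test used the control probe sets or the probe sets shared by several adult globin genes, and signals in them differed between the groups.

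The control probe sets were the first such signal. The 18S ribosomal RNA 3' probe set was 422-fold higher on the knockout-labelled arrays, 19 of the 27 poly-A control probe sets had every knockout-labelled value above every wild-type-labelled one, and the largest hybridisation control fold was 4.16. One scaling factor per array is argued against for the 18S 3' probe set, since its fold was 101 times the largest hybridisation control fold. The wild-type-labelled values of this probe set are dim (54.0 to 187), but the lowest knockout-labelled value was still 161 times the highest of them. The hybridisation controls, at 1.6- to 4.16-fold, are not covered by this comparison, so such a factor stays open for them. The main gene tests made no adjustment for such a factor. Degraded RNA stays open: the ratios of 3' to 5' signal for Gapdh and beta-actin, tried first, come from probe sets near the top of the scale, and of 2 dimmer transcripts tried next the larger ratio, knockout-labelled over wild-type-labelled, was 1.08 with too wide an error. Separate processing of the groups stays open and may account for it. The 70.4% of poly-A control probe sets that separated the groups are the pattern itself, so this share cannot decide. The wild-type-labelled means of the poly-A control probe sets are also dim (2.245 to 52.56). No gene of interest lies among the 18S, poly-A and hybridisation control probe sets, while the housekeeping controls include probe sets for the transferrin receptor (Tfrc). The design gives no batch to test within.

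Hepatocyte and stromal markers were higher, and lymphoid and granulocyte markers lower, on the knockout-labelled arrays. Scaling that depends on intensity is argued against, because under cyclic loess the hepatocyte list still lay 4.31 log2 units above all genes. A different mixture of cells in the samples, in spite of the CD71 and Ter119 sort, may account for it and stays open. At least 78.9% of the tested members of both the hepatocyte and the lymphoid list passed in their direction. Alb stood at 40107 ± 11164 and Vpreb1 at 8588 ± 2910 (SD, n = 3) on the arrays where they were high. These shares and signals are the pattern itself, so they cannot decide for or against a mixture. A smaller share of erythroid cells alone would have raised all other cell types, and they moved apart. A difference in developmental stage or source also stays open. In a fit without an intensity filter 80% of a 15-gene fetal-stage list was higher, 5 of the 12 higher genes from wild-type signals under the main filter. But Lin28a and Lin28b were lower (-3.42 and -2.82), Lin28b with means under the filter in both groups (44.88 and 8.884). Imprinted genes of that list are also expressed by hepatocytes and stroma.

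Embryonic globins were higher on the knockout-labelled arrays, and the largest fold of a probe set shared by several adult globin genes was 15.4. Cross-hybridisation of adult globin RNA stays open. The lowest embryonic fold was 11.2 times the highest of the 4 adult globin probe sets below the top of the scale (1.48- to 4.91-fold). These 4 are dim on wild-type-labelled arrays (94.3 to 381), where the shared ones read 3760 to 23525. Their folds may therefore not follow adult globin RNA, and the comparison cannot decide. The Hbb-bh1 probe sets read 14.0 to 23.2 on wild-type-labelled arrays, so the adult globin RNA present there gave them little signal. A larger share of mature erythroid cells in the sort may contribute and was not decided: the membrane skeleton list gave a camera adjusted p of 0.0552, and over 22 alternatives it ran from 0.0021 to 0.681 and passed upward in 12. Loss of Eklf itself, the difference that the design names, stays open for the cell marker and globin patterns and cannot be separated here from the cell mixture or from processing.

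With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Of the 10 splits 1, the real one, gave as many called genes as the real 6232, and the highest of the others gave 0.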

How the results depend on the processing

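Cyclic loess and the fit with knockout-labelled array 1 alone were chosen after seeing the data, and the other alternatives before. Over 20 alternatives, 2973 of 3079 values of named genes kept their direction and their side of the threshold, 64 lost the call, 25 gained it and 17 reversed. For gene lists, over 22 alternatives with both other set tests, 563 of 658 values did, 40 lost the call, 25 gained it and 30 reversed. Many named genes were picked for large changes or small p in these data, which favours their keeping the call. Of all 6232 genes called as deposited, 6227 kept call and direction with an offset of 16 and 4815 without wild-type-labelled array 1. After quantile normalization 4253 did, after cyclic loess 4221 and after median centring 3746. With the replicate number as a block, 6277 genes were called (2706 lower, 3571 higher) and 19 lists. Deviations of same-numbered arrays correlated at 0.081, 0.036 and 0.09, and those of differently numbered arrays at -0.1 to 0.016. All are small, but the same-numbered ones were the highest, so a pairing by number was neither shown nor excluded. Left-out arrays gave 4875 to 6217 called genes.

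Fewer genes were called higher after quantile normalization (2224), cyclic loess (2292) and the 60th percentile filter (2133, with fewer genes tested). Median centring gave 6133 lower and 1085 higher genes and a Klf1 difference of -1.20 (adjusted p = 0.0128), the largest shift of Klf1 seen. Testing every probe set gave 11838 calls, 4243 lower and 7595 higher, over more features. Knockout-labelled array 1 as the lone array of its group, assumed to vary like the others, gave 2603 calls, 1339 lower and 1264 higher. An adjusted p under 0.01 left 3776, 1672 lower and 2104 higher, and at least a 2-fold change left 4024, 1404 of them lower. With an estimated correlation 0 gene lists passed (8 at an unadjusted p under 0.05), against 18 with camera's preset one and 19 with fry. Signal over background limits dim genes: 1090 calls have 1 group under the filter. The cause was not tested, except where fewer genes or arrays or more features entered.

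Of called named genes and lists, reversals were the ribosomal protein list after quantile normalization (-0.046), Tfrc after median centring (-0.35) and Stat2 as the mean of its probe sets (-0.060). Over all genes, that mean gave 5032 calls, 39 of them opposite to the call reported, and no other alternative gave any. The other named reversals had not passed the test, and did not pass after reversal. Quantile normalization turned Uty (-0.12) and Hba-a1 (-0.097), and cyclic loess turned them too (-0.25 and -0.13). Median centring turned Uty (-0.21), Hba-a1 (-0.066), Ank1 (-0.14), Cdkn1a (-0.25), Cdkn1b (-0.43) and Icam4 (-0.44). It lowers every gene by the same amount (all-gene median 0.14 as deposited, -0.68 after it), so small positive differences, that of Tfrc among them, turn with it. Knockout-labelled array 1 alone turned Klf1 (0.22), Uty (-0.44), E2f4 (0.37) and Cdkn1a (-0.40). Uty turned without knockout-labelled array 2 (range over left-out arrays -0.29 to 1.13) and Kdm5d without array 3 (-2.76 to 0.12). For lists, the direction is that of the set test, and the value is the list's median minus that of all genes, which can differ in sign from it. Under quantile normalization it turned for erythropoietin signalling (-0.20), inhibitors of cyclin-dependent kinases (0.16), mitosis (0.013) and interferon response (-0.20), and under cyclic loess for the same lists (-0.24, 0.11, 0.0047 and -0.23). Fry turned erythropoietin signalling (-0.48), kinase inhibitors (0.24) and sex-linked genes (-0.65). Median centring turned kinase inhibitors (0.24), macrophage markers (-0.30) and sex-linked genes (-0.65). No intensity filter turned erythroid transcription factors (-0.15), kinase inhibitors (0.087) and interferon response (-0.17), and testing every probe set turned the same lists (-0.18, 0.060 and -0.19). The 60th percentile filter turned erythropoietin signalling (-0.28) and kinase inhibitors (0.12), and array weights the latter (0.33). With arrays left out, erythroid transcription factors turned without wild-type-labelled array 2 (-0.13) or knockout-labelled array 1 (-0.054; range -0.13 to -0.0043), kinase inhibitors without knockout-labelled array 1 (0.13 to 0.33) and sex-linked genes without knockout-labelled array 3 (-1.65 to 0.23). Knockout-labelled array 1 alone turned autophagy genes (-0.11) and interferon response (-0.15).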

Other observations

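The tests here were chosen only after the results were seen, apart from those on named genes.

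Of 23 genes of the major histocompatibility complex and its peptide loading, 5 were higher and 6 lower on the knockout-labelled arrays and 12 did not pass. Tap1, a peptide transporter, fell by 2.41 (adjusted p = 8.62e-05), and H2-D1, a class I heavy chain, fell by 1.30. Class II genes did not move together: H2-Aa fell by 1.89, H2-DMa fell by 1.68 and Cd74, the invariant chain, fell by 1.43, but H2-Ab1 (0.44), H2-Eb1 (-0.67), H2-Eb2 (1.01), H2-DMb2 (0.73) and H2-Oa (-0.57) did not pass. H2-Q10, which encodes a class I molecule secreted by the liver, rose from 62.9 ± 5.89 to 1027 ± 288 (SD, n = 3) and H2-Q5 rose by 4.12, both from a wild-type signal under the filter. Class I H2-K1 (-0.02) did not pass, nor did B2m at 0.25 ± 0.22 (SE, adjusted p = 0.365).

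Of 9 replication-dependent histone genes tested, 4 rose, 0 fell and 5 did not pass, with H1f4 up from 109 ± 19.9 to 6121 ± 651 (SD, n = 3) and H2bc22 up by 2.97, while H1f2 did not pass at -0.02 ± 0.27 (SE, adjusted p = 0.96). Of the wider histone and chromatin list fixed in advance, 11 of 24 fell and 2 rose.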
